A study of Mus musculus with 3 samples.

How the data were processed

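The series mapped the transcriptional co-activator Yap1 in mouse heart by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Wild-type male C57BL/6J mice had a sham operation or transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. Per the labels' protocols, hearts were taken 7 days after surgery, frozen and passed to a company that made the libraries. The series' design gives 3 mice per operation. There was 1 anti-Yap1 library for sham, 1 for TAC and 1 input library made from a pool of both operations. Whether each anti-Yap1 library pooled its 3 mice is not given in the sources used here.

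Reads were aligned with BWA and regions were called with MACS 1.4.2 on the mm10 build, per the submitters' processing notes. The deposited table has 1 row per merged region over both anti-Yap1 libraries, and 32930 called intervals were merged into its 22020 regions. For each library it gives the average signal over the region and the highest signal within it, per the file headers. It also gives a mark for whether the region was called in that library, with the authors' listed genes, distance to the transcription start, position class, and counts of promoters and CpG islands. The table's column names carry the operation, which matched each column to 1 library. They also carry a number after the operation that the labels do not explain. The maximum signal was a whole number in 100% of regions in both libraries. How the authors scaled the signal of the libraries to each other, the peak threshold, the fragment length and the read depth are not given in the sources used here. Depth is therefore unknown, and whether the call marks are complete could not be checked. If the libraries were left at different depths, a ratio between them carries that difference. A region entered the table only when it was called in at least 1 library, so weak regions were selected by their calls. The input signal was not analysed here.

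The ratio of each region was log2((TAC + 1)/(sham + 1)) of the deposited average signal, with a pseudocount of 1. Fold values below are on this scale and understate differences of weak regions. Regions past a fixed size of 1.5-fold were counted on the deposited scale, and again after subtracting the median ratio of all regions. A region counted as promoter when the table counted a promoter to it. Among such regions listed for 1 gene, the 1st to 99th percentile of the distance to the start ran from -8033 to 4160 bp, so the class is wide. Other regions took the authors' position class. Distances to the start run from the midpoint of a region, so a region classed as upstream or in a gene can span the start.

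The table named 13464 gene symbols. Of these, 12191 were current symbols in a RefSeq gene table of the GRCm38.p6 assembly, 868 matched by a synonym and 405 did not match and were kept as given. Each gene was represented by the region with the highest mean signal over both libraries. Because 6179 regions (28.1%) were listed for 2 or more genes, some values are shared between neighbouring genes. Coordinates are those of the authors' table on mm10.

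There were 22 gene lists with 424 different genes, covering Yap1 and Hippo biology, cardiomyocyte function, metabolism, matrix and signalling, markers of the other cell types of the heart, and hepatocyte and neuronal genes as an off-tissue comparison. For each list the median ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these libraries and is not a test. A list was called below or above when it lay outside the 2.5 to 97.5 percentile band. That band was set after the data were examined, and 1.1 of 22 lists would lie outside it by chance. Intervals of medians are 95% order-statistic intervals over regions or genes, and intervals of shares are 95% Wilson intervals. Both leave out variation between mice.

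Named genes followed a rule. It took the 10 regions with the largest and the 10 with the smallest ratio among regions with a listed gene and a mean signal at or above the median of all regions (8.98). It also took the 5 strongest regions of each library. In every list it took the 2 genes with the highest and the 2 with the lowest ratio. For the YAP and TEAD, Hippo and hypertrophic lists the 6 strongest genes were added, and Yap1 and Tead1 were named whatever their values. Some genes that these rules take are not reported here. Any other gene named here was chosen after its values were seen. The groups, lists, named-gene rule, fixed size and most alternative settings were set before the data were examined. Alternatives covered the pseudocount, weak regions, maximum signal, centring, quantile normalization, sex chromosomes, regions called in both libraries, a 2-fold size, peak strength, promoter distance, and the way regions were assigned to genes. Another 4 were added after seeing the data. They matched random lists also on promoter and CpG island class (with 5 signal bins), kept only regions called in both libraries for the lists and for the counts, and kept only regions listed for 1 gene.

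The calculations were tested on simulated data with 22020 regions, of which 200 were changed 2-fold. They recovered 96% of the higher and 93% of the lower regions, with 0.898% of the other regions past the fixed size. The sarcomere list regions were also shifted, by -0.25 on the log2 scale, and count among these other regions. The shifted list had a percentile of 0, and 1 list that was not shifted fell outside the band. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Sequence motifs were not analysed here.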

Results

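Yap1 binding was compared between hearts after a sham operation and hearts 7 days after TAC, to map where this Hippo pathway effector sits in the normal and in the pressure-loaded heart. The data are average and maximum ChIP signal at 22020 regions for 1 sham and 1 TAC library. Regions had a median length of 2115 bp and ranged from 484 to 33397 bp. With 1 library per operation there are no replicates, so no difference below was tested against variation between mice, and higher or lower describes these 2 libraries only. Read depth is unknown.

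Yap1 signal was lower in the TAC library at nearly all regions. The sham library had a call at 21271 regions (96.6%, 95% Wilson interval 96.4 to 96.8%) and the TAC library at 10718 (48.7%, 48.0 to 49.3%). Both libraries had a call at 9969 regions (45.3%, 44.6 to 45.9%), sham alone at 11302 (51.3%, 50.7 to 52.0%) and TAC alone at 749 (3.40%, 3.17 to 3.65%). Of those called in TAC alone, 152 had a sham signal at or above TAC, so the missing sham call there does not mean a lower sham signal. The median average signal was 10.6 in sham (quartiles 8.94 and 13.1) and 7.46 in TAC (5.91 and 9.20). The median log2 ratio of TAC to sham was -0.54 (95% interval over regions -0.54 to -0.53), a signal 1.45-fold higher in sham, and 20830 regions (94.6%) had a ratio below 0. The ratio also stayed below 0 in the regions called in both libraries, at a median of -0.46.

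As deposited, 107 regions were at least 1.5-fold higher in TAC and 9468 at least 1.5-fold lower. Relative to the median ratio of all regions, 974 were higher and 508 lower, so that 65.7% of the regions past this size were higher in place of 1.12%. The scaling between the libraries therefore sets which direction is the more frequent, and the gene and list ratios below, printed on the deposited scale, are set against the median of all genes (-0.50 over 13448 genes). The rank order of regions was shared in part, with a Spearman correlation of 0.67 between the libraries across regions, which are not independent replicates.

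The strongest average signal in sham lay at Dynll1, which encodes a dynein light chain, on chromosome 5 from 115299444 to 115302401. It had 44.9 in sham and 23.5 in TAC. Irf2bp2, a transcriptional co-repressor gene, followed with 41.1 and 25.2, and was the strongest region in TAC. The sham ranking continued with the RNA helicase gene Ddx5 (39.2 in sham), the translation initiation factor gene Eif4a2 (38.2) and Ska2 (36.4). The TAC ranking continued with the histone H3.3 gene H3f3b (24.7 in TAC), the cell cycle inhibitor gene Cdkn1a (24.7), Dynll1 and Ddx5. By maximum signal, the highest region in sham was at Amotl2, an angiomotin family gene whose product binds Yap1. This region on chromosome 9, from 102713297 to 102734572, reached 275 in sham and 139 in TAC, where it ranked 3.

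**Figure D1:**
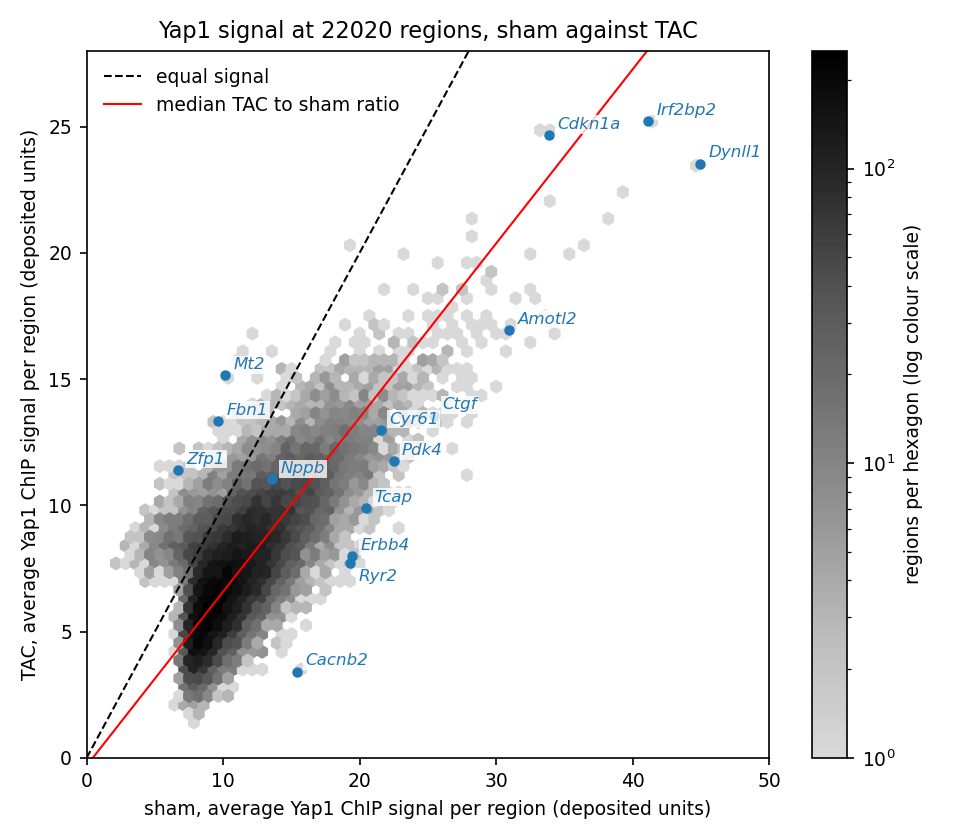
Average Yap1 ChIP signal of each region in sham (x axis) and TAC (y axis), in the deposited units, with hexagons shaded by the number of regions on a log colour scale. The dashed line marks equal signal and the red line the median ratio; blue points mark regions of named genes. Most of the 22020 regions lie below the dashed line, Dynll1 and Irf2bp2 are among the strongest, and the region in Cacnb2 is far below the red line.

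Regions at promoters had a higher ratio of TAC to sham signal than regions inside genes. Promoters were counted to 9779 regions (44.4%, 43.8 to 45.1%), another 7515 (34.1%) lay in a gene, 225 (1.02%) upstream, 844 (3.83%) downstream, and 3657 (16.6%) had no listed gene. CpG islands were counted to 7936 regions (36.0%). The median log2 ratio was -0.49 at promoters (-0.50 to -0.48) and -0.59 in genes (-0.60 to -0.59). Among regions called in both libraries, promoter regions had a higher ratio than all other regions in each of 5 signal classes, by 0.08 to 0.12, and by 0.05 to 0.09 among regions without a CpG island. The promoter share was 57.4% of regions called in both libraries, 33.8% of those called in sham only and 32.7% of those called in TAC only. Of the 508 regions at least 1.5-fold lower relative to the median, 73 (14.4%, 11.6 to 17.7%) were at promoters and 253 (49.8%) in genes. Of the 974 higher ones, 346 (35.5%, 32.6 to 38.6%) were at promoters, so both sets had a lower promoter share than the other regions (45.6%). These shares were not matched on signal, and promoters made up 63.2% of regions with a mean signal at or above the median. A lower share in both sets may therefore reflect weaker signal.

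Most genes of the sarcomere, calcium handling and metabolism lists had a Yap1 region. Of the 21900 protein-coding genes in the RefSeq table, 11651 (53.2%) had one. All 27 sarcomere and Z-disc genes and all 22 fatty acid oxidation genes had a region, as had 23 of 25 genes of calcium handling and ion channels, 16 of 18 cardiac transcription factors, 22 of 22 glycolysis genes and 23 of 24 respiratory chain genes. The AP-1 (18 of 18), TGF-beta (22 of 22), housekeeping (15 of 15) and actin and focal adhesion (26 of 27) lists were as full. By contrast, 4 of 14 hepatocyte genes and 3 of 14 neuronal genes had a region, 25% of both lists together (12.7 to 43.4%). Markers of other heart cells lay between, with 13 of 15 endothelial, 8 of 12 smooth muscle and pericyte, 6 of 14 fibroblast and 5 of 17 macrophage and leukocyte genes. The hypertrophic and fetal cardiac list had 13 of 18 (72.2%, 49.1 to 87.5%), growth factor and PI3K signalling 18 of 23, matrix and fibrosis 14 of 24, cell cycle 19 of 23, YAP and TEAD targets 18 of 22 and the Hippo list 21 of 25. All 5 of those macrophage and leukocyte genes shared their region with a neighbouring gene. Sharing was common in other lists too, at 18 of 23 respiratory chain, 15 of 27 sarcomere, 11 of 22 fatty acid oxidation and 11 of 15 housekeeping genes. It held for 3 of 4 hepatocyte and 2 of 3 neuronal genes, but for only 7 of 23 calcium handling and 4 of 22 TGF-beta genes.

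**Figure D2:**
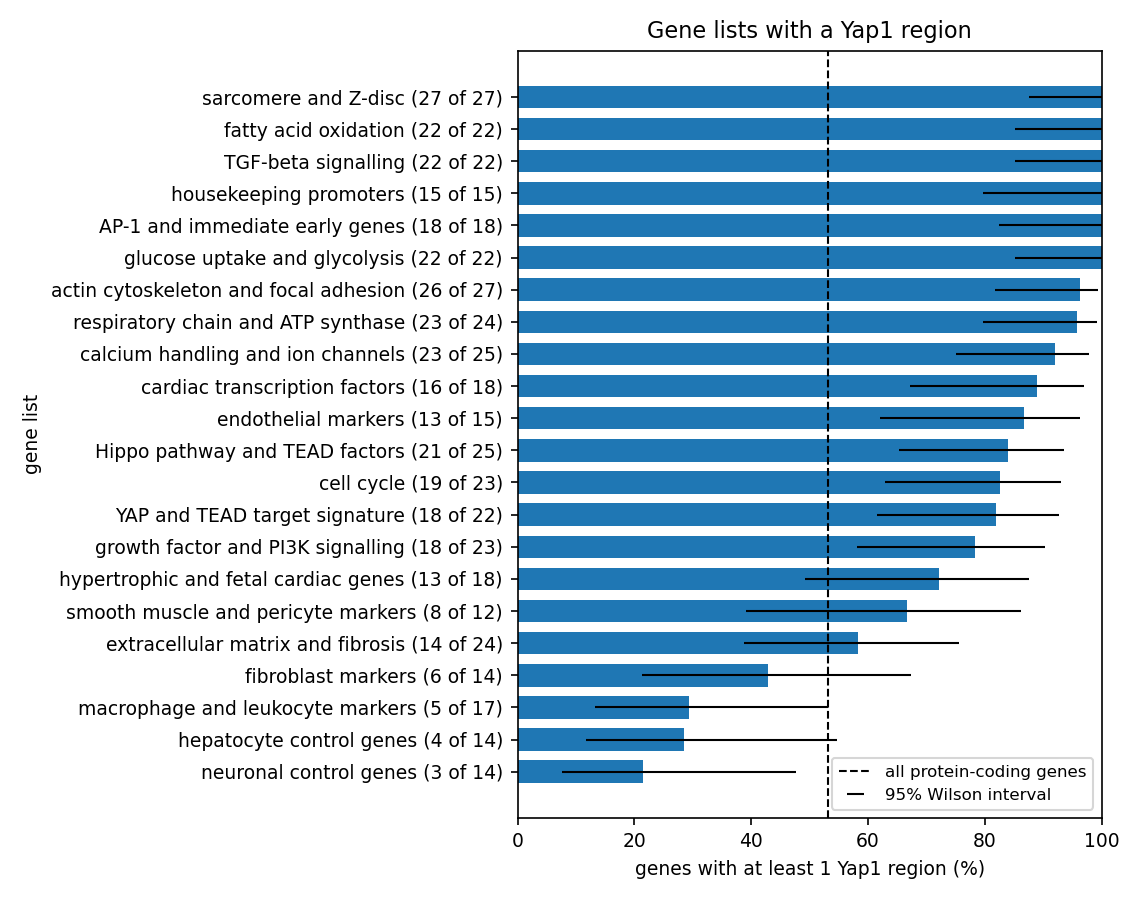
Percent of each list's genes with at least 1 Yap1 region in either library (x axis, bars), with 95% Wilson intervals as black lines and the number of genes beside each list name. The dashed line marks all protein-coding genes at 53.2%; the sarcomere and fatty acid oxidation lists are at 100%, and the hepatocyte (28.6%) and neuronal (21.4%) lists to its left.

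Genes of the YAP and TEAD target signature had a median signal percentile of 70.6 among all genes with a region, which did not set them apart. Fatty acid oxidation (70.7), glycolysis (74.5), actin and focal adhesion (76.3), housekeeping (85.3) and AP-1 (88.0) genes lay higher, and the other lists lower. As a group the signature's ratio of TAC to sham was not outside that of matched random lists. The 18 of 22 genes with a region had a median signal of 15.9 in sham and 10.5 in TAC, and a median log2 ratio of -0.63 (-0.79 to -0.52). All genes had a median of -0.50, and 14 of the 18 lay below it. The list's percentile among matched random lists was 5.27, inside the band. It was 0.13 with only regions called in both libraries, 0.545 with stronger regions and 0.89 with only regions near the start, all below the band, but 34.2 by maximum signal, 38.4 with the mean over a gene's regions and 47.8 with only regions listed for 1 gene. Ctgf, a matricellular protein gene much used as a readout of Yap1, had 25.5 in sham and 13.5 in TAC (log2 ratio -0.86) in a region on chromosome 10 from 24592840 to 24598124 at its start. Amotl2 had 31.0 and 17.0, Cyr61 21.5 and 13.0, Gadd45a 20.9 and 10.9, Lats2 20.2 and 10.8, and Ptpn14 19.8 and 11.01. Nuak2 (-0.20) and Tgfb2 (-0.10) had the highest ratios. The Nuak2 region was listed downstream, 18862 bp from its start.

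The Hippo pathway and TEAD list covered the kinases, adaptors and DNA-binding partners of Yap1, and as a group it did not stand apart. Its 21 of 25 genes with a region had a median log2 ratio of -0.51 (-0.73 to -0.33) and a percentile of 41.9, with 11 below the median of all genes. The percentile was 4.245 by maximum signal, nearer the lower edge of the band, and 65.8 with the mean over a gene's regions. Yap1 had a region on chromosome 9 from 8002546 to 8005315, with 16.2 in sham and 9.12 in TAC (log2 ratio -0.76) and a call in sham only. This region spans the start of Yap1, with the midpoint 666 bp inside the gene. Tead1, which encodes a DNA-binding partner of Yap1, had 19.4 and 10.1 (-0.88) in a region on chromosome 7 from 112677803 to 112682440, called in both libraries. Tead3 had 19.02 and 14.6, Wwtr1, the gene of the Yap1 paralog Taz, 18.5 and 12.8, and Stk4 17.8 and 12.1. The Tead3 region was listed downstream, 22101 bp from its start, and for 3 genes. Sav1 was at -0.13, and Dchs1, at 0.15, was the 1 gene of the list with more average signal in TAC. By maximum signal Sav1 (0.40) and Fat4 (0.36) were higher in TAC as well.

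Hypertrophic and fetal cardiac genes, many of which are re-expressed under load, did not stand apart as a group. Like nearly all regions they were lower in TAC, at a median log2 ratio of -0.60 (-0.86 to -0.36) over 13 of 18 genes. Of these, 8 lay below the median of all genes, and the list had a percentile of 17.3, inside the band. The percentile was 2.57 by maximum signal, just inside the band, and 41.8 with only regions listed for 1 gene. Nppa, Acta1, Tnni1, Timp1 and Cilp had no region. Nppb, the gene of B-type natriuretic peptide, had 13.6 in sham and 11.02 in TAC (-0.28). Its region of 2944 bp spans the start, with the midpoint at -194 bp. Rcan1, a calcineurin regulator, was at -0.22. Xirp2 (-1.19) and Acta2 (-0.88) had the lowest ratios, and neither was called in TAC. The strongest were Ctgf, Myl4 with 19.05 and 13.7, Xirp1 with 16.8 and 10.3, Myh7 with 15.9 and 9.06, Nmrk2 with 14.3 and 9.13, and Nppb. The Myh7 region was listed downstream of the gene and for 4 genes in all.

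Calcium handling, sarcomere and cardiac transcription factor genes had the lowest ratios of TAC to sham, with growth factor genes. Calcium handling and ion channel genes had a median log2 ratio of -0.85 (-0.91 to -0.65), 1.80-fold higher in sham, and 20 of 23 genes lay below the median of all genes. Ryr2, the sarcoplasmic calcium release channel gene, had 19.3 in sham and 7.73 in TAC (-1.22), in a region not called in TAC. Kcnj11, a potassium channel gene, had 18.2 and 8.10 (-1.08) in a region called in both libraries. Hcn4 (-0.47) and Kcna5 (-0.30) were closer to other genes, but Kcna5 was at -0.81 by maximum signal. Sarcomere and Z-disc genes had a median of -0.73 (-0.79 to -0.63), with 25 of 27 below the median of all genes. Tcap, a titin-binding protein gene, had 20.5 and 9.89 (-0.98), and the ventricular myosin light chain gene Myl2 25.6 and 12.8 (-0.94) in a region called in TAC only. The midpoints of these regions were upstream, at -6089 bp for Tcap, in a region listed for 4 genes, and at -7169 bp for Myl2. Synpo2l (-0.48) and Csrp3 (-0.41) had the highest ratios. Cardiac transcription factors had a median of -0.68 (-0.73 to -0.60), with 13 of 16 below. Zfpm2, the gene of a GATA4 cofactor, had 11.7 and 4.95 (-1.09), Nkx2-5 13.4 and 6.61 (-0.92), Hopx was at -0.40 and Mef2c at -0.22.

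Fatty acid oxidation and growth factor genes were also below matched random lists. Fatty acid oxidation genes had a median log2 ratio of -0.62 (-0.72 to -0.54), with 18 of 22 below the median of all genes. Pdk4, a kinase gene that limits glucose oxidation, had 22.5 in sham and 11.7 in TAC (-0.88), and Cpt1b, the gene of the muscle carnitine palmitoyltransferase, 17.1 and 9.40 (-0.80). Ppara (-0.43) and Mlycd (-0.35) had the highest ratios. Both regions were listed downstream, that of Ppara 75604 bp from its start and for 3 genes, that of Mlycd 29144 bp and for 2. Growth factor and PI3K signalling genes had a median of -0.68 (-0.79 to -0.61), with 15 of 18 below. Erbb4, the neuregulin receptor gene, had 19.5 and 7.98 (-1.19), the insulin receptor gene Insr 18.0 and 9.70 (-0.83), Hbegf was at -0.39 and Mtor at -0.19. These 5 lists had percentiles of 0 (calcium handling), 0 (sarcomere), 0.37 (cardiac transcription factors), 0.29 (growth factor) and 1.98 (fatty acid oxidation), and no list lay above the band, where 1.1 of 22 lists would lie outside it by chance. By maximum signal, which is the highest value within each region, only the calcium handling list stayed below it (0.5), with 4.46 for sarcomere, 4.56 for fatty acid oxidation, 5.53 for cardiac transcription factors and 14.1 for growth factor genes. With the mean over a gene's regions, growth factor genes (10.4) and cardiac transcription factors (5.31) were inside it, as were fatty acid oxidation genes with a pseudocount of 5 (2.64), the gene listed at the front (6.31), regions listed for 1 gene (10.1) and random lists matched also on promoter and CpG island class (4.99).

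**Figure D3:**
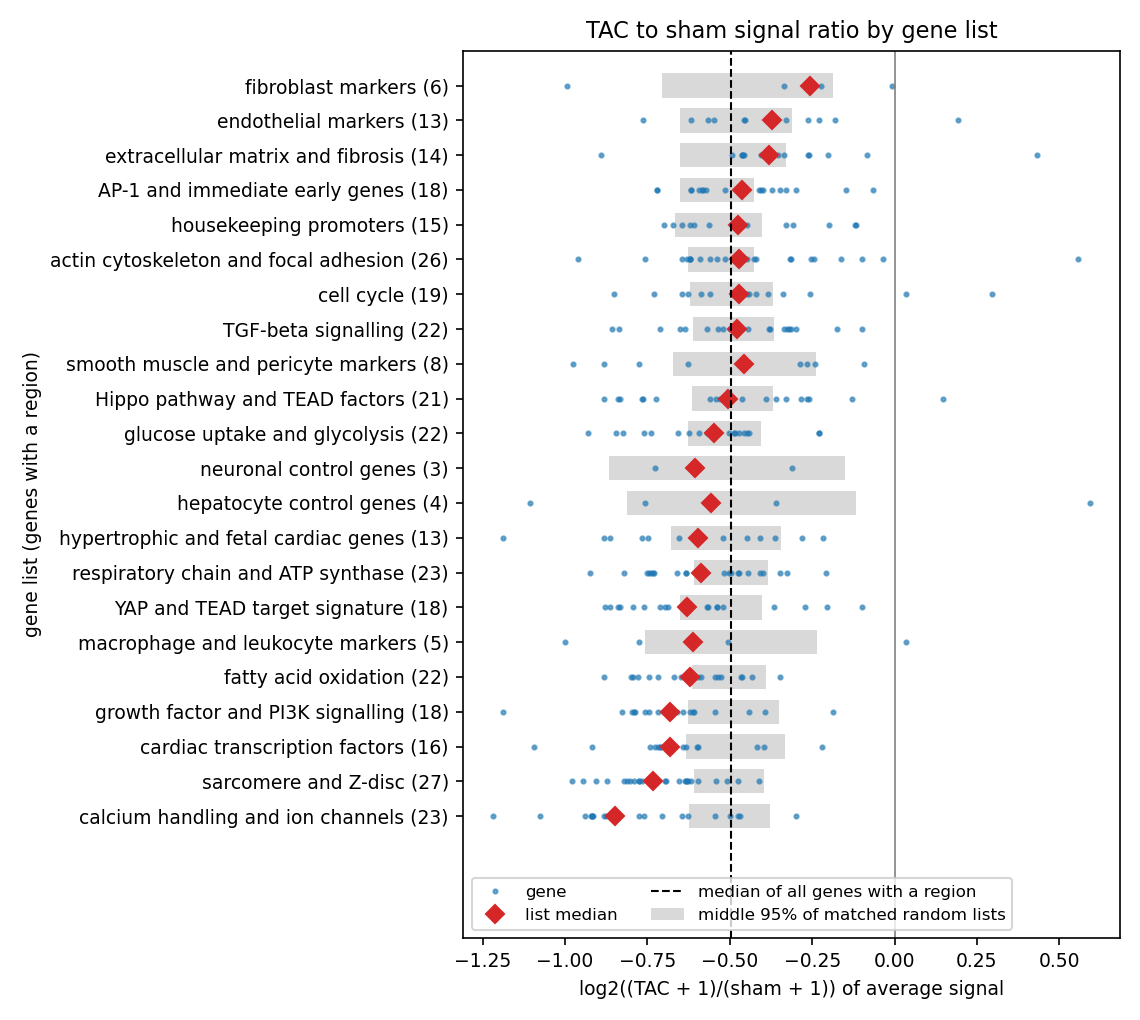
Log2 ratio of TAC to sham average signal (x axis) for each gene list (y axis, with the number of genes that have a region); blue points are genes, red diamonds list medians and grey bars the middle 95% of 10000 random lists matched on signal. The dashed line marks the median of all genes at -0.50; 5 list medians lie left of their grey bar, with calcium handling and ion channels at -0.85, and none lies right of it.

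Matrix, endothelial and fibroblast genes lay above the median of all genes, smooth muscle and pericyte markers were split around it with 4 below and 4 above, and macrophage and leukocyte markers lay below it, all inside the band. Extracellular matrix and fibrosis genes had a median log2 ratio of -0.38 (-0.46 to -0.20) over 14 of 24 genes, with 1 below the median of all genes and a percentile of 91.1. This was 99.3 with the mean over a gene's regions, but 60.5 with the region nearest the start (8 genes) and 64.1 with regions called in both libraries (6 genes). Fbn1, the fibrillin gene, had 9.63 in sham and 13.3 in TAC (0.43) and was called in TAC only. Loxl2 was at -0.08, Sparc at -0.49 and Col5a1 at -0.89. Endothelial markers had a median of -0.37 (-0.57 to -0.23) and a percentile of 90.5, from Tie1 (0.19) and Cdh5 (-0.18) to Tek (-0.62) and Egfl7 (-0.76). The Egfl7 region was called in TAC only, and Tie1 was at -0.07 by maximum signal. Fibroblast markers had a median of -0.26 and a percentile of 93.1 over 6 genes, from Mfap5 (-0.01) and Tcf21 (-0.22) to Pdgfra (-0.33) and Gsn (-0.99). By maximum signal the fibroblast list lay above the band, at 98.6. Smooth muscle and pericyte markers had a median of -0.46 and a percentile of 50.7, from Cspg4 (-0.09) and Cnn1 (-0.24) to Acta2 (-0.88) and Notch3 (-0.98). This percentile ranged widely, from 2.07, below the band, with only regions listed for 1 gene to 93.1 with only the gene listed at the front of each region. Macrophage and leukocyte markers had a median of -0.61 and a percentile of 18.6 over 5 genes, from Tyrobp (0.03) and Cd14 (-0.51) to Spi1 (-0.77) and Cd79a (-0.998). By maximum signal this list lay above the median of all genes (by 0.213, percentile 88.1), and by the mean over regions near it (-0.0135). The Spi1 region was that of its neighbour Mybpc3.

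The other lists lay inside the band. Respiratory chain and ATP synthase genes had a median log2 ratio of -0.59 and a percentile of 5.72, which was below the band with the mean over a gene's regions (1.26) and the region nearest the start (2.48) and 49.7 by maximum signal. They ran from Uqcrc2 (-0.21) and Cox7a1 (-0.33) to Atp5o (-0.82) and Cox5a (-0.92). The Cox7a1 region was listed downstream, 10214 bp from its start, and for 2 genes. Glucose uptake and glycolysis genes were at -0.55 and 30.8, from Slc2a1 (-0.23) and Tpi1 (-0.23) to Pgam2 (-0.85) and Pfkfb1 (-0.93). TGF-beta signalling genes were at -0.48 and 56.0, with Bmpr2 at -0.18, Ski at -0.84 and Bmpr1a at -0.86. AP-1 and immediate early genes carried strong signal in both libraries, with medians of 18.2 in sham and 12.3 in TAC, and had a ratio of -0.46 and a percentile of 91.8. Egr3 (-0.06) and Myc (-0.15) were highest, and Nr4a1 (-0.72) and Junb (-0.72) lowest. Actin cytoskeleton and focal adhesion genes were at -0.47 and 86.7, from Tln2 (0.56) and Rhob (-0.04) to Rock2 (-0.76) and Tns1 (-0.96), whose region was called in TAC only. Cell cycle genes were at -0.47 and 66.1, with more signal in TAC at Cdk1 (0.30) and Top2a (0.04), and the lowest ratios at Cdkn1b (-0.73) and Ccne1 (-0.85). By maximum signal Cdk1 was at 0 and Top2a at -0.21. Housekeeping genes were at -0.47 and 83.7, from Eef1a1 (-0.12) and B2m (-0.12) to Rpl13a (-0.70). Of the off-tissue genes, the hepatocyte list was at -0.56 and 34.2, from G6pc (0.59) and Fgb (-0.36) to Apoa1 (-0.76) and Ttr (-1.11). The neuronal list was at -0.60 and 35.5, with Slc17a7 at -0.31, Eno2 at -0.60 and Syt1 at -0.73.

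Among regions of at least median signal with a listed gene, the largest ratios were at Zfp1, Cables1, Synm, Mt2, Sncaip, Nbas, Arnt2, Il4ra, Snhg6 and Rbms3, at log2 ratios from 0.69 down to 0.44. The Zfp1 region, in the gene on chromosome 8 from 111658037 to 111659683, had 6.71 in sham and 11.4 in TAC. The region of the metallothionein genes Mt2 and Mt1 had 10.2 and 15.1 and was called in both libraries. It is 3135 bp long and spans the Mt2 start, with the midpoint at -510 bp. Of these 10 regions, 6 were not called in sham. By the same rule, the smallest ratios were at Cacnb2, Mylk4, Camta1, Irs1, Rgs6, Sorcs2, 6330403A02Rik, Agap1, Brwd1 and Ntn1, from -1.89 up to -1.31. All 10 had their midpoint inside a gene, 1 of them within 5000 bp of the start, and none was called in TAC. The region in Cacnb2, a calcium channel subunit gene, on chromosome 2 from 14917052 to 14918355, had 15.4 in sham and 3.41 in TAC. Another region of Cacnb2, which represents the gene in its list, had 17.7 and 8.90.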

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

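No paired analysis was possible because each operation has 1 library. Of the values that carry a comparison, 79 stayed and 37 moved, and of the other list values 209 stayed and 11 moved. A value stayed when it was within the 95% interval of a median or share, or within 1.5 times for a count. No called value changed sign, which was checked only for the median ratio of all regions and the 5 called lists. The macrophage, hepatocyte and neuronal lists had too few genes for an interval, so their ratios counted as stayed whatever their values. The causes were not tested unless named. Depth is unknown, there are no replicates, input subtraction was not run because the table has no input column, and sequence motifs were not run because no genome was used here. Centring leaves list results unchanged by construction. Matching random lists also on promoter and CpG island class leaves list medians unchanged in the same way, and these counted as stayed. The median log2 ratio was -0.588 with a pseudocount of 0.1, -0.383 with 5, -0.508 in stronger regions (mean signal at or above the median), -0.547 by maximum signal, -0.0260 after quantile normalization and -0.463 in regions called in both libraries; centring sets it to 0. Regions at least 1.5-fold higher in TAC numbered 20 with a pseudocount of 5, 3 among stronger regions, 212 by maximum signal, 974 after centring, 901 after quantile normalization, 13 at 2-fold, and 216 in regions called in both libraries relative to their own median, a setting chosen after seeing the data. Regions at least 1.5-fold lower numbered 3105 with a pseudocount of 5, 4212 among stronger regions, which are fewer, 508 after centring, 307 after quantile normalization, 1127 at 2-fold and 73 in that added setting. Calls in both libraries made up 74.3% of stronger regions and 83.1% of regions with a maximum in the upper quartile, calls in sham only 23.5% and 16.0%, and calls in TAC only 2.20% and 0.878%. Promoters made up 31.8% of regions by a start within 1000 bp and 63.2% of stronger regions. By maximum signal 1 list lay below the band and 1 above it (fibroblast markers), and with the mean over a gene's regions 1 lay above (extracellular matrix, percentile 99.3, against 60.5 by the region nearest the start and 64.1 in regions called in both libraries). Relative to all genes, cardiac transcription factors were at -0.231 by the region nearest the start, and growth factor genes at -0.109 by maximum signal and -0.0842 by the mean over regions. Over 11 alternatives, calcium handling stayed below the band in 11, sarcomere genes in 10, cardiac transcription factors and growth factor genes in 9 each and fatty acid oxidation in 6. All 5 lists were below other genes in 11 of 11, which include the class matching that cannot change a list median. With stronger regions, 88.8% of the pooled sarcomere, calcium handling, cardiac transcription factor, fatty acid oxidation and respiratory chain genes and 7.14% of hepatocyte and neuronal genes had a region, the latter also 7.14% within 5000 bp of the start.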

Other observations

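Several genes carried a large number of Yap1 regions, a feature chosen after the values were seen. Rbm20, the gene of a cardiac splicing regulator, had 32 regions upstream of or inside it, and Cacna1c, the L-type calcium channel gene, had 28. Nfia had 24, Nav2 and Palld 23 each, and Fhod3 and Prdm16 21 each. The median log2 ratio of these regions was -0.69 for Rbm20, -0.76 for Palld and -0.81 for Fhod3, against -0.54 for all regions. Of 636 genes with at least 5 such regions, 413 had a median ratio below that of all regions. Location was not separated from the number of regions here. Regions in genes had a median of -0.59 in the whole table, against -0.49 at promoters, so all regions are an unlike baseline. The longest regions lay at Ehd1 (33397 bp), Zbtb16 (32553 bp), Tns1 (31921 bp) and Txnip (31016 bp, a region listed for 3 genes).

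Calls and signal did not always go together, and whether the sham call marks in the table are complete was not tested. Of the 749 regions called in TAC only, 152 (20.3%) had a sham signal at or above that in TAC, with medians of 13.4 in sham and 10.2 in TAC. Among them were Myl2, Tpm1 with 24.7 in sham and 15.6 in TAC, Pnpla2 with 29.7 and 19.2, and Klf13, whose maximum was 162 in sham and 103 in TAC. Another region called in sham lay within 5000 bp of 43 of the 152 (28.3%), and of 145 of the other 597 (24.3%). Of 11302 regions called in sham only, 41 had a TAC signal at or above sham.

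For the patterns below, the test on regions called in both libraries was set out before its result was seen, and the other tests were chosen after seeing the results. The lower signal in TAC over nearly all regions may come from a difference in library scale, from lower enrichment in the TAC library or from less Yap1 on chromatin after TAC. A single scale factor would leave the ratio of maximum to average signal alike in both libraries, and in the strongest of 10 equal signal classes the TAC value was 0.978 of the sham value. Lower enrichment would leave the strongest regions with a lower ratio than the middle ones, and they were at -0.0829 relative to class 5 of the 10 on the log2 scale. The weakest class was lower still, at -0.93 against -0.61 in the strongest, both without a pseudocount. Among regions called in both libraries the ratio instead fell with signal over 5 classes. It went from -0.27 to -0.55 at promoters and from -0.36 to -0.63 at other regions. Weak regions were selected by their calls, which may shape both trends. None of these values decides, because depth and signal outside the regions were not used here, so scale, enrichment and operation cannot be told apart for this pattern.

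The 5 lists below matched random lists were weighed against the makeup of the lists and against calls. With random lists matched also on promoter and CpG island class, 4 of the 5 stayed below the band, all but fatty acid oxidation at 4.99, which argues against that makeup as the whole cause. This matching used 5 signal bins in place of 20, so part of a shift in percentile may come from the coarser matching on signal. With only regions called in both libraries, 5 of 5 stayed below it, so the low ratios were not confined to regions without a TAC call. This restriction could change little, because most genes of the calcium handling, sarcomere and fatty acid oxidation lists were already represented by a region called in both. Under it 25 of 27 sarcomere, 21 of 23 calcium handling and 22 of 22 fatty acid oxidation genes kept a region. A smaller share of cardiomyocyte nuclei in TAC hearts is a candidate explanation: the pooled markers of 4 non-myocyte types had a median log2 ratio of -0.37 and a percentile of 96.81, inside the band. On 32 genes in all, no type lay outside the band by itself in the main setting, with percentiles of 90.5 for endothelial, 93.1 for fibroblast, 50.7 for smooth muscle and pericyte and 18.6 for macrophage markers. By maximum signal the fibroblast list lay above the band, at 98.6, with endothelial markers at 55.7, macrophage markers at 88.1 and smooth muscle and pericyte markers at 26.5. With only regions called in both libraries the medians relative to all genes were 0.0548 for 10 endothelial genes (percentile 60.2) and 0.175 for 4 fibroblast genes (67.6), against 0.124 for 13 and 0.239 for 6 in the main setting. Smooth muscle and pericyte markers rose to 0.227 for 3 genes (84.0), from 0.0401 for 8, and macrophage markers were at -0.144 for 3 genes (26.1), from -0.115 for 5. Of the 58 markers, 5 are also in another list. On these few genes cell makeup and a change within cardiomyocytes cannot be told apart.

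Whether the spread of the ratio between single regions may be counting variation was left open. In binomial draws that treat each maximum as a count of fragments with 1 common share, the SD of the log2 ratio was 0.45, and the observed SD was 0.943 of that. The observed SD was below the lowest of 100 draws, so maxima do not vary like such counts and the draws give no floor. On average signal, 4.42% of regions were at least 1.5-fold higher and 2.31% lower relative to the median. In simulated data 0.898% of the regions not changed 2-fold were past this size, a set that includes the shifted sarcomere regions. The simulation assumed Poisson counts of 200 bp fragments. With fragment length and depth unknown, counting variation and other differences cannot be told apart for single regions.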
